A study of Solanum lycopersicum with 12 samples.

How the data were processed

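RNA of tomato leaves (Solanum lycopersicum, the dwarf cultivar Micro-Tom) was measured by sequencing in 12 libraries, 3 from plants before heat and 3 each after 24, 48 and 96 h at 42 °C, and each library was placed in its group by its own label. The labels number the libraries 1 to 3 within a group but do not say that these came from separate plants, so the p-values measure the spread between these samples, which may be partly technical. The labels' extraction text speaks of leaves and of fruit, and all 12 samples are given as leaves. Unheated leaves were taken at 0 h alone, so each comparison holds a difference in plant age besides the one in heat.

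Per the submitters' processing notes, reads were handled with Trimmomatic, HISAT2, Cufflinks and HTSeq. The notes give no order or version for these tools, and the genome build and annotation release are not given in the sources used here. The authors deposited one table of raw counts per gene and one table of FPKM values for the same 34075 genes, with gene descriptions, Gene Ontology (GO) terms and KEGG pathways beside each gene. The authors also deposited tables of mapping and read quality, from which the percent of mapped and multiply mapped reads, the GC percent and the number of reads per library were taken. Gene names are those that the authors' tables pair with each identifier. They read as names of the best match in other species, so members of gene families are named with some uncertainty, and reads shared between close paralogs, or between overlapping and antisense genes, cannot be assigned here because the counting settings are not given. No genome coordinates were used.

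Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with edgeR's default filter for the 4 groups, which left 20797 genes, libraries were scaled by trimmed mean of M values (TMM), and one quasi-likelihood model with a term per group was fitted to all 12 libraries. Each heat time was compared with 0 h, 48 h with 24 h and 96 h with 48 h, and a joint F-test asked whether a gene differed from 0 h at any heat time. Adjusted p-values are Benjamini-Hochberg values over all tested genes, a gene was called at an adjusted p under 0.05, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Means and standard deviations (SD) of single genes are over TMM-scaled counts scaled to a common library size (CPM) of 3 libraries. A comparison of 96 h with 24 h was added after the data were seen, because neighbouring times gave almost no calls.

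Before the data were examined, 38 gene lists were fixed as word patterns on the gene descriptions, 33 of them processes of heat-stressed leaves (10 marked as core) and 5 of them meant as markers of other tissues or of organelle and ribosomal RNA. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 38 lists within a comparison. Camera with an estimated correlation and the self-contained test fry were run beside it. Per list, called members were counted with p-values adjusted over all genes and adjusted over the list alone. The 926 GO terms and 103 KEGG pathways with 15 to 500 tested members were tested with camera in the same way. Of the tested genes, 14722 carried a GO term and 4626 a pathway. The pattern for HSP70 also takes in one protein whose name, HSC80, belongs to the HSP90 family. The pattern for heat shock transcription factors also matches multiprotein bridging factors, so its list can hold genes that are not heat shock factors. That for ethylene also matches words such as methylene, so its list can hold genes unrelated to ethylene. That for abscisic acid and dehydration takes in every gene described as a protein phosphatase 2C, so its list can hold genes unrelated to abscisic acid. The pattern for organelle and ribosomal RNA took in 8 genes of nuclear intron maturases and ribosomal RNA processing proteins among its 10, so it does not measure those transcripts.

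The genes named in the text follow a rule fixed at the same time. Against 0 h it takes the 5 genes with the largest rise and the 5 with the largest fall, and between heat times 3 and 3. All are called genes with an informative description, at least 10 CPM in the higher group and no overlap between libraries of the 2 groups. Each list adds its most abundant member and its called member with the largest change. List members are taken only against 0 h and from 24 h to 96 h. Where all 3 libraries of a group held 0 counts, the fold is a bound against 3 counts over the group. Where a group held 1 to 3 counts in total, the ratio is given with a 95% exact binomial counting interval. Such intervals and bounds cover counting error only, and fitted log2 fold changes of these genes depend on the prior count and are no bounds. Setting members with 0 counts at their bound moved no list median against 0 h by more than 0.0362.

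Principal components were computed on centred log2 CPM of the tested genes. Overlaps and correlations between the comparisons with 0 h share the control libraries. For this reason 20 sets of 12 libraries were simulated without any change, all drawn from the control means, the controls included. Genes were drawn independently, so deviations that genes share in the real controls are absent. Alternatives fixed before the data were examined were DESeq2 size factors and upper quartile scaling, no low-count filter or at least 10 CPM in 3 libraries, DESeq2 1.42.0, a fit on the 2 compared groups alone, the replicate number as a block, the 50 most abundant genes left out, an adjusted p under 0.01, a 2-fold minimum, limma with an intensity trend on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Chosen after seeing the data were the omission of replicate 3 of 48 h with replicate 2 of 96 h, the omission of replicate 1 of 24 h with replicate 2 of 48 h, log2(FPKM + 0.1) for the lists, and the omissions for the sample structure and the overlaps. A 2-library group left by an omission was assumed to vary like the others. Leaving out a library of a group outside a comparison keeps the compared libraries, and changes the shared estimate of spread and the adjustment over genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

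The steps were tested on simulated data drawn from the real means and library sizes. For 24 h against 0 h, with 100 genes changed 2-fold and 100 changed 4-fold among 20594 tested, edgeR called 25% of the former and 71% of the latter with 7 false calls. For 96 h against 48 h, over 20593 genes, the shares were 17% and 74% with 5 false calls. DESeq2 called 46% of the 2-fold changes in both, with 47 and 59 false calls. A list of 30 further genes was raised 2-fold in each simulation and not counted among the false calls. The real comparisons with 0 h called far more genes than were changed here, so these shares need not hold for them. A chi-square test per gene found every pair of libraries of one group further apart than sampling noise, with at least 19.5 per gene, so no library was counted as a duplicate.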

Results

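Leaf transcripts of Micro-Tom tomato were counted in 12 libraries, 3 taken before heat and 3 after each of 24, 48 and 96 h at 42 °C, to follow how expression changes with the length of heat stress. No unheated leaves were taken after 0 h, so heat, plant age and any difference in the hour of sampling change together. The control libraries held 19161094, 20381341 and 18512586 gene counts in replicates 1, 2 and 3. The 24 h libraries held 18936930, 19534396 and 18923556, the 48 h libraries 20486213, 19819720 and 19592206 and the 96 h libraries 20808466, 19538030 and 18370928. Between 96.04% and 98.27% of the reads of a library were mapped, and 22806 to 23653 genes had at least 1 count.

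The first principal component, with 41.2% of the variance, separated the controls from all heated leaves and placed the heat times in order. Its mean ± SD over 3 libraries was -103.7 ± 10.7 at 0 h, 4.89 ± 14.9 at 24 h, 31.0 ± 17.3 at 48 h and 67.8 ± 10.3 at 96 h. The second component (17.6%) spread libraries within groups. Replicate 3 of 48 h lay at -65.0 and replicate 2 of 96 h at -68.3, apart from the others of their groups. Correlations of log2 CPM across genes ran from 0.914 to 0.978 within groups, from 0.822 to 0.925 between controls and heated leaves and from 0.888 to 0.972 between heat times, and 4 of the 9 heated libraries were closest to one of their own time. Control replicate 2 differed from the other controls in photosynthetic transcripts. The centred mean log2 CPM of the light-harvesting list was 1.03 in it, against -1.25 and -1.74 in control replicates 1 and 3.

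**Figure D1:**
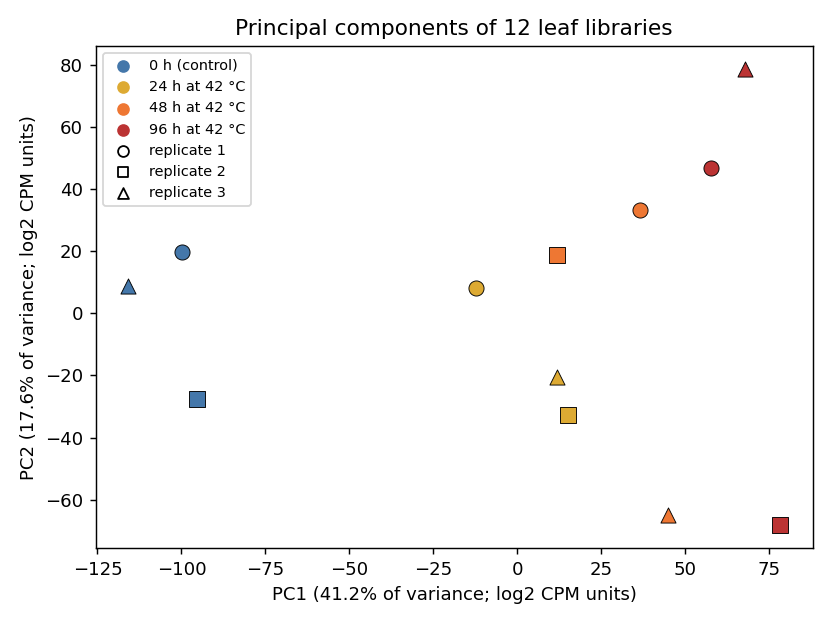
Each point is 1 of the 12 leaf libraries on the first (41.2% of variance) and second (17.6%) principal components of centred log2 CPM, coloured by hours at 42 °C and shaped by replicate. The control libraries lie at -95.5 or lower on the first component and all 96 h libraries at 57.6 or higher.

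Over the whole time course 5099 of 20797 tested genes (24.5%) differed from 0 h at one heat time or more in the joint edgeR test. The number fell to 3034 without control replicate 3 and 3133 without control replicate 1.

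After 24 h of heat the list of small heat shock proteins, the chaperones that hold unfolding proteins, was higher than at 0 h and that of WRKY transcription factors, regulators of defence and stress responses, lower. These calls are by camera at a preset correlation between genes, and neither held with an estimated one (adjusted p = 0.980 and 0.0873). The 22.0 kDa class IV heat shock protein HSP22.0 (Solyc03g113930.3) rose from 0.109 ± 0.0508 to 10.9 ± 12.2 CPM (mean ± SD, n = 3 each), a 93.7-fold change (log2 fold change 6.55 ± 1.37 SE, edgeR adjusted p = 0.0124). WRKY53 (Solyc08g008280.3) fell from 246 ± 91.0 to 7.82 ± 0.774 CPM (-4.97 ± 0.270, adjusted p = 1.95e-05). The cold- and dehydration-response factor DREB1A (Solyc03g124110.2) went from 43.8 ± 25.7 CPM to 0 counts in all 24 h libraries, at least 852-fold lower (adjusted p = 0.00124). A cytochrome P450, CYP72A219 (Solyc07g055460.3), rose by 5.16 ± 1.07 (7.23 without control replicate 3) to 13.2 ± 9.15 CPM. In all, edgeR called 935 genes higher and 1457 lower, of which 518 and 1039 changed at least 2-fold.

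Of 26 small heat shock proteins 12 rose, 1 fell and 13 did not pass (17 and 4 adjusted over the list alone), with a median log2 fold change of 2.88 (camera adjusted p = 0.00144, 0.980 with an estimated correlation). The mean of the list was uneven between libraries, at 2.21, 0.04 and 0.85 in replicates 1, 2 and 3 of 24 h against -0.57 or lower in the controls. The 22.7 kDa class IV protein Solyc01g102960.3 rose to 104 ± 134 CPM from 2.13 ± 0.839 (5.60 ± 1.28, adjusted p = 0.0186), a call lost without control replicate 1 (5.52), 2 (5.39) or 3 (5.95). Replicate 1 of 24 h held 257.9 CPM and the others 13.5 and 39.9, and without it the fold change was 3.65. That of HSP22.0 was 5.07 without the same library, and its call was lost without control replicate 3 (6.24). The most abundant member, HSP18.5-C (Solyc09g011710.4), was at 342 ± 78.1 CPM against 529 ± 92.7 at 0 h and did not pass (-0.63 ± 0.256, adjusted p = 0.140). Of 23 members of the HSP70 list 1 rose and 2 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.366). This list passed as lower without replicate 1 of 24 h (0.0224), in a range of 0.0224 to 0.867. HSP70-8 (Solyc09g075950.1) rose by 3.19 ± 0.685 (adjusted p = 0.0139, 2.33 without replicate 1 of 24 h), a call lost without control replicate 3 (3.16). None of 10 HSP90 and HSP100 proteins or 27 chaperonins was called (camera adjusted p = 0.160 and 0.966, edgeR for single genes), and of 86 DnaJ and BAG co-chaperones 3 rose and 6 fell (3 and 7 adjusted over the list alone, 0.883). In the heat shock factor list of 25 genes none rose and 3 fell (0 and 3, 0.652), among them HSFA4C (Solyc07g055710.3, -2.18 ± 0.408, adjusted p = 0.00699). The HSP90 and HSP100 list passed as higher without replicate 2 of 24 h (0.0145), in a range of 0.0145 to 0.598. HSFA3 was at 109 ± 32.3 and 105 ± 3.74 CPM.

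WRKY factors had the lowest camera p among the lists that fell. Of 58 measured, 25 fell and none rose (33 and 1 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.14e-14, 0.0873 with an estimated correlation). WRKY2 (Solyc07g066220.3), the most abundant, fell by 0.93 on the log2 scale to 102 ± 5.89 CPM (adjusted p = 0.0107), a call lost without replicate 2 of 24 h (-0.88). Genes annotated with the response to chitin, a fungal cell wall elicitor, moved the same way, with 46 of 96 down and 2 up (camera adjusted p = 2.14e-17, 0.790 with an estimated correlation). In the abscisic acid and dehydration list of 134 genes 24 fell and 1 rose (25 and 4 adjusted over the list alone, median -0.21, camera adjusted p = 0.0112, 0.806 with an estimated correlation). CYP707A2 (Solyc08g005610.3), which breaks down abscisic acid, fell from 309 ± 183 to 2.55 ± 1.43 CPM (-6.92 ± 0.651, adjusted p = 0.000201). In the ethylene list of 140 genes 28 fell and 8 rose (31 and 16 adjusted over the list alone, camera adjusted p = 0.127). It passed as lower without replicate 1 of 24 h (0.0402) or replicate 2 of 24 h (0.0237), in a range of 0.0237 to 0.306. ERF109 (Solyc01g108240.3) was lower by a ratio of 1032 (95% counting interval 285 to 8529, 2 counts at 24 h) and ERF025 (Solyc06g035700.1) by 640 (219 to 3105, 3 counts, with a fitted log2 fold change of -9.17, and -9.99 without replicate 1 of 24 h). In the jasmonate and wound list of 74 genes 11 fell and none rose (11 and 1), while the median was 0.20 and the camera test pointed down (adjusted p = 0.412). Of 92 pathogenesis-related proteins 3 rose and 4 fell (camera adjusted p = 0.972).

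The auxin list passed as higher at 24 h. Of 136, 13 rose and 7 fell (16 and 9 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0112, 0.970 with an estimated correlation). This call was lost with upper quartile scaling (0.0502) and with the filter at 10 CPM (0.134) in a range of 0.0106 to 0.134 over the settings. GH3.6 (Solyc12g005310.2), an enzyme that conjugates auxin, was higher by a ratio of 46.2 (12.5 to 387, 2 counts at 0 h, both in control replicate 2). Without that library the fitted log2 fold change went from 5.29 to 8.07. Of 31 aquaporins, water channels of membranes, 1 rose and 1 fell (1 and 0, median 0.48, camera adjusted p = 0.0112, 0.435 with an estimated correlation). PIP2-1 (Solyc11g069430.2) rose from 253 ± 12.6 to 498 ± 44.8 CPM (0.98 ± 0.192, adjusted p = 0.00912). The list of cytosolic ribosomal proteins passed as lower, with 11 down and 3 up of 235 (2 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 1.34e-05, 0.980 with an estimated correlation). Without control replicate 2 this was not called (0.278, in a range of 3.75e-13 to 0.278 over the 12 omissions).

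Photosynthetic genes were not called as groups at 24 h. Of 38 light-harvesting chlorophyll a/b proteins 1 fell, of 33 photosystem and electron transport subunits 2 rose, and of 30 Calvin cycle enzymes and 26 chlorophyll synthesis genes 1 rose and 1 fell each (camera adjusted p = 0.284, 0.160, 0.638 and 0.160). Without control replicate 2 all 4 lists passed as higher (6.83e-06, 3.24e-07, 0.00295 and 6.83e-06, the lowest values over the 12 omissions, whose highest were 0.984, 0.984, 0.984 and 0.741). Without replicate 1 of 24 h the light-harvesting, photosystem and chlorophyll synthesis lists passed too (0.00304, 0.00252 and 0.0175). The Calvin cycle list had a median of -0.11 while its test pointed up. CAB7 (Solyc10g006230.3), the most abundant light-harvesting protein, was at 3829 ± 1550 CPM against 2877 ± 2140. HEMA1 (Solyc01g106390.3), a member of the chlorophyll synthesis list, fell from 147 ± 46.1 to 12.5 ± 1.45 CPM (-3.55 ± 0.256, adjusted p = 8.72e-05).

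Among the remaining lists at 24 h, 5 hydrogen peroxide and superoxide scavenging genes of 41 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.380), including a minor catalase (Solyc01g100630.3, 2.17 ± 0.359, adjusted p = 0.00365, 2.77 without control replicate 3), while the abundant catalase Solyc02g082760.3 was at 2067 ± 539 and 2112 ± 662 CPM. Of 54 glutathione S-transferases 1 rose and 4 fell (1 and 3 adjusted over the list alone, 0.366), of 54 genes of chlorophyll breakdown, senescence and autophagy 3 fell (0.127, 0.0111 without control replicate 2, range 0.0111 to 0.343), and of 99 phenylpropanoid and flavonoid genes 2 rose and 12 fell (17 down and 7 up adjusted over the list alone, 0.218). SAG21 (Solyc06g009140.3), a late embryogenesis abundant-like protein, fell by 4.02 on the log2 scale from 205 ± 76.9 CPM. None of 27 endoplasmic reticulum folding genes and 53 proteasome subunits was called by edgeR (camera adjusted p = 0.532 and 0.366). The proteasome list passed as lower without replicate 1 of 24 h (9.32e-05), in a range of 9.32e-05 to 0.984.

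The rest of the lists did not pass at 24 h by camera with all libraries. Histones and cell division genes had 6 up and 1 down of 149 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0686), and passed as higher without control replicate 2 (0.000275), replicate 1 of 24 h (0.0341) or replicate 3 of 48 h (0.0445), in a range of 0.000275 to 0.495. Ribosomal proteins of the plastid and mitochondrial type had 2 up of 66 (0.236, and 1.28e-06 without control replicate 2, range 1.28e-06 to 0.984). Cell wall loosening and pectin genes had 10 up and 12 down of 125 (0.440), with a median of 0.23 and a mean of -0.07. Raffinose, trehalose and proline synthesis had 2 down of 28 (0.127), starch and sucrose genes 2 up and 4 down of 57 (0.288), carotenoid synthesis 1 up and 1 down of 18 (0.638), splicing factors 3 up and 3 down of 78 (0.883) and the circadian clock 3 down of 18 (0.127). Of 21 transposon-related transcripts 2 rose, with a median of 0.57 or 0.54 with members at 0 counts set at their bound (0.0686). This list passed without control replicate 1 (0.0431), replicate 1 of 24 h (0.0270), replicate 2 of 24 h (0.0491), replicate 1 of 48 h (0.0232), replicate 2 of 48 h (0.0390), replicate 3 of 48 h (0.0326), replicate 1 of 96 h (0.0462) or replicate 3 of 96 h (0.0374), in a range of 0.0232 to 0.115. None of the 6 list calls at 24 h held with an estimated correlation. The test fry, which asks whether a list's genes move one way on balance, also passed 3 of them and not those of small heat shock proteins (0.162), auxin (0.162) and cytosolic ribosomal proteins (0.462). It passed 3 lists that camera did not.

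The edgeR count of 2392 changed genes fell to 1191 without replicate 2 of 24 h, 1335 without replicate 3 of 24 h and 1426 without control replicate 3, while DESeq2 called 3931. The share of calls that were higher was 39.1%, and 54.9% under upper quartile scaling, which moved the median of all genes from 0.01 to 0.12 on the log2 scale.

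**Figure D2:**
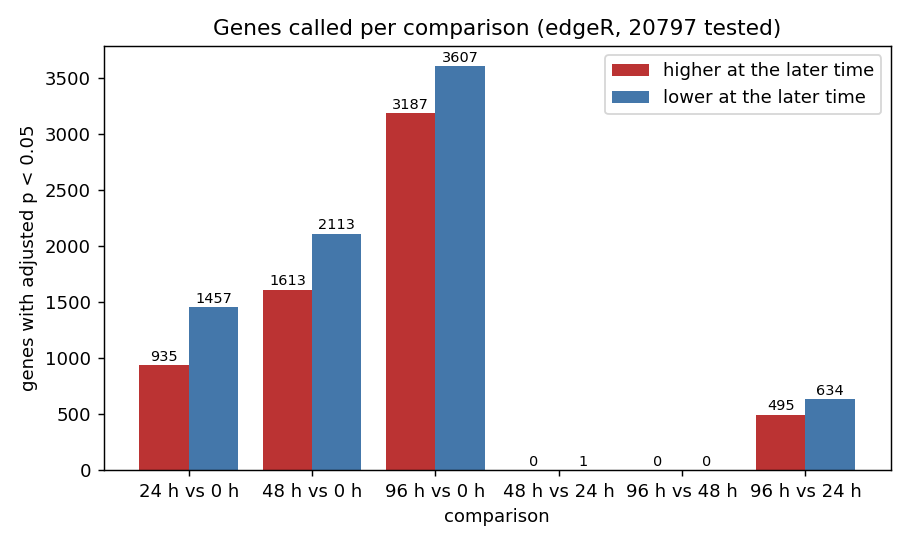
Bars give the number of genes called higher (red) or lower (blue) at the later time of each comparison on a linear axis from 0, at an edgeR adjusted p under 0.05 among 20797 genes. Calls against 0 h run from 935 higher and 1457 lower at 24 h to 3187 and 3607 at 96 h, and comparisons of neighbouring heat times give 1 and 0 calls in total.

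After 48 h the WRKY list was lower and the auxin list higher than at 0 h by camera at the preset correlation, and neither with an estimated one (adjusted p = 0.123 and 0.826). WRKY53 fell to 5.88 ± 0.286 CPM (log2 fold change -5.38 ± 0.275 SE, n = 3 per group, edgeR adjusted p = 1.06e-05). DREB1A Solyc03g026270.3 went from 27.8 ± 22.7 CPM to 0 counts, at least 572-fold lower, and DREB1D (Solyc08g007820.1) fell by 9.45 on the log2 scale from 81.0 ± 46.9 CPM (adjusted p = 6.24e-05). A miraculin-like protein (Solyc11g022590.1), of a family of protease inhibitors, rose from 11.9 ± 13.9 to 369 ± 94.4 CPM (4.95 ± 1.08, adjusted p = 0.0110, 6.53 without control replicate 2). CYP72A219 rose to 26.8 ± 17.2 CPM (6.18 ± 1.09, adjusted p = 0.00385, 8.24 without control replicate 3). In all, 1613 genes were called higher and 2113 lower, 912 and 1399 of them at least 2-fold.

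Of the 58 WRKY factors 30 fell and none rose at 48 h (32 and 1 adjusted over the list alone, median -1.20, camera adjusted p = 5.11e-13, 0.123 with an estimated correlation). In the abscisic acid and dehydration list of 134 genes 29 fell and 6 rose (32 and 9, median -0.24, camera adjusted p = 0.00753, 0.826 with an estimated correlation), with CYP707A2 at -7.26 ± 0.663. In the ethylene list 32 fell and 11 rose (34 and 13, camera adjusted p = 0.0740). It passed without control replicate 1 (0.0374), control replicate 2 (0.0183), replicate 1 of 24 h (0.0412), replicate 2 of 24 h (0.0305), replicate 3 of 24 h (0.0371), replicate 1 of 48 h (0.0416), replicate 3 of 48 h (0.0335), replicate 1 of 96 h (0.0367), replicate 2 of 96 h (0.0396) or replicate 3 of 96 h (0.0353), in a range of 0.0183 to 0.107. ERF025 was lower by a ratio of 1031 (285 to 8516, 2 counts at 48 h). Its fitted log2 fold change went from -9.76 to -12.31 without replicate 1 of 48 h, which held both counts. The jasmonate and wound list had 9 down and 2 up (8 and 2), with a median of 0.11 and a camera test that pointed down (adjusted p = 0.654). Its member TIFY5A (Solyc08g036640.3), a repressor of jasmonate signalling, changed by -6.56 on the log2 scale (-5.94 without control replicate 3). Response to chitin had 55 of 96 genes down and 4 up (camera adjusted p = 1.13e-17, 0.560 with an estimated correlation), and plant-pathogen interaction 47 of 161 down and 6 up (camera adjusted p = 5.74e-07, 0.988 with an estimated correlation). A lignin-forming anionic peroxidase (Solyc11g018774.1) changed by -8.92 on the log2 scale from 63.3 ± 47.9 CPM (-8.16 without control replicate 2).

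Of 136 auxin genes 28 rose and 8 fell (32 and 10 adjusted over the list alone, median 0.41, camera adjusted p = 0.00411, 0.826 with an estimated correlation). With the filter at 10 CPM the list did not pass (0.0791, range 0.000620 to 0.0791 over the settings). GH3.6 was higher by a ratio of 250.0 (68.9 to 2070, 2 counts at 0 h). Its fitted log2 fold change went from 7.75 to 10.52 without control replicate 2, which held both counts. Aquaporins had 4 up and 1 down of 31 (8 and 1, median 0.59, camera adjusted p = 0.0408, 0.764 with an estimated correlation), a call lost without control replicate 1 (0.0599), control replicate 3 (0.0516), replicate 3 of 24 h (0.0571) or replicate 1 of 48 h (0.169), and with upper quartile scaling (0.0711), in ranges of 0.00998 to 0.169 over the omissions and 0.00785 to 0.0711 over the settings. The list of chlorophyll breakdown, senescence and autophagy passed as lower, 7 down and 1 up of 54 (7 and 1, median -0.33, camera adjusted p = 0.00863, 0.929 with an estimated correlation, 0.0735 without replicate 3 of 48 h, range 0.000413 to 0.0735). SAG21 fell by 4.79 on the log2 scale. The proteasome list passed as lower with 2 down of 53 (0 adjusted over the list alone, median -0.28, camera adjusted p = 0.00610, 0.929 with an estimated correlation). It was also lost without replicate 1 of 48 h and on log2(FPKM + 1) (0.0614 without replicate 1 of 48 h, range 4.94e-05 to 0.0614, 0.0739 on log2(FPKM + 1), range 5.43e-08 to 0.0739 over the settings).

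Of the small heat shock proteins 12 rose and 5 fell at 48 h (15 and 5 adjusted over the list alone), with a median of 2.26 and a camera adjusted p of 0.0740, which passed without replicate 1 of 48 h (0.00364), replicate 1 (0.0375) or 2 (0.0368) of 24 h in a range of 0.00364 to 0.205. Their mean was again uneven, at -0.59, 1.59 and 0.43 in the 3 libraries. HSP22.0 rose to 8.001 ± 9.75 CPM (6.11 ± 1.36, adjusted p = 0.0124, 4.39 without replicate 2 of 48 h), a call lost without control replicate 3 (5.80), and HSP18.5-C fell to 247 ± 58.4 CPM (-1.10 ± 0.259, adjusted p = 0.0158), a call lost without control replicate 3 (-0.96), replicate 1 (-1.08) or replicate 3 (-0.95) of 48 h. The HSP70 list had 1 up and 4 down (camera adjusted p = 0.208), the HSP90 and HSP100 list no call by edgeR (0.654), and the heat shock factor list 3 up and 3 down (0.398). HSFA4C fell by 2.51 on the log2 scale (adjusted p = 0.00258). The light-harvesting list had 1 down, the photosystem list 2 up, the Calvin cycle list 2 up and 1 down and the chlorophyll synthesis list 1 up and 1 down (camera adjusted p = 0.304, 0.156, 0.429 and 0.0740). Without control replicate 2 all 4 passed as higher (8.12e-05, 3.17e-06, 0.00219 and 9.24e-06, against highest values over the omissions of 0.849, 0.885, 0.982 and 0.4998), and without replicate 2 of 48 h the photosystem and chlorophyll synthesis lists passed (0.0425 and 0.00907). The Calvin cycle list had a median of -0.05 while its test pointed up. HEMA1 fell by 3.86 on the log2 scale (adjusted p = 4.06e-05) and CAB7 was at 3438 ± 773 CPM.

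Cytosolic ribosomal proteins had 6 up and 5 down at 48 h (camera adjusted p = 0.654) and passed as lower without control replicate 3 (0.0124) and as higher without control replicate 2 (0.00610), in a range of 0.00610 to 0.714. The clock gene GIGANTEA (Solyc04g071990.3) fell by 2.998 on the log2 scale to 4.19 ± 0.797 CPM, and soluble starch synthase 1 (Solyc03g083090.4) by 1.85 to 18.04 ± 3.06 CPM. The minor catalase Solyc01g100630.3 rose by 2.70 ± 0.363 (adjusted p = 0.000884, 3.29 without control replicate 3), the scavenging list as a whole having 5 up and 2 down of 41 (camera adjusted p = 0.981). Phenylpropanoid genes had 19 down and 5 up of 99 (19 and 6, camera adjusted p = 0.0740, 0.0145 without control replicate 2 and 0.0335 without replicate 3 of 48 h, range 0.0145 to 0.133), and the glutathione S-transferase GSTF11 (Solyc02g081340.3) fell by 3.82 on the log2 scale (adjusted p = 0.000691). None of the 6 list calls at 48 h held with an estimated correlation. Of these, fry did not pass the proteasome (0.351) and chlorophyll breakdown lists (0.0752), and it passed 5 lists that camera did not.

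The edgeR count of 3726 fell to 2132 without replicate 3 and 2299 without replicate 1 of 48 h, to 2158 without control replicate 3 and 2415 without control replicate 1, and to 2370 in a fit on the 2 groups alone. The share of higher calls was 43.3%, and 62.6% under upper quartile scaling with a median of all genes of 0.18 in place of 0.02.

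After 96 h the number of called genes was the highest of the 3 times, with 3187 genes higher and 3607 lower than at 0 h (1803 and 2276 at least 2-fold). By camera at the preset correlation 16 lists passed, and none of them held with an estimated correlation, where the adjusted p was 0.180 for WRKY factors, 0.832 for cytosolic ribosomal proteins and 0.772 for the others. The test fry did not pass 8 of the 16, the light-harvesting (0.173), photosystem (0.124), Calvin cycle (0.164) and cytosolic ribosomal lists (0.390) and, at 0.0744 each, the chlorophyll synthesis, chaperonin, proteasome and plastid and mitochondrial type ribosomal lists. It passed 7 lists that camera did not. A CBS domain protein (CBSCBSPB4, Solyc12g032930.3) went from 0 counts to 23.6 ± 5.59 CPM, at least 432-fold higher (edgeR adjusted p = 9.85e-05, n = 3 per group). Dihydroflavonol 4-reductase (Solyc02g085020.4), an enzyme of anthocyanin synthesis, fell from 81.6 ± 19.6 to 0.175 ± 0.209 CPM (log2 fold change -8.79 ± 0.662 SE, adjusted p = 3.66e-05, -10.39 without replicate 2 of 96 h). WRKY40 (Solyc03g116890.3) fell from 99.2 ± 66.1 to 0.969 ± 0.647 CPM (-6.66 ± 0.808, adjusted p = 0.000279, -6.06 without control replicate 3 and -7.34 without replicate 1 of 96 h).

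The light-harvesting list passed as higher at 96 h, with a median of 1.02 (camera adjusted p = 0.000680, 0.772 with an estimated correlation), although by single genes 3 of 38 rose and 1 fell (0 and 1 adjusted over the list alone). CAB7 was at 5354 ± 646 CPM against 2877 ± 2140, which did not pass (0.90 ± 0.493, adjusted p = 0.186), control replicate 2 standing at 5349 CPM and replicates 1 and 3 at 1752 and 1531. Of 33 photosystem and electron transport subunits 2 rose (2 adjusted over the list alone, median 0.75, camera adjusted p = 0.000680), and of 30 Calvin cycle enzymes 6 rose and 1 fell (4 and 1, median 0.31, camera adjusted p = 0.00970, 0.0740 without control replicate 1 and 0.0965 without control replicate 3, range 3.78e-06 to 0.0965). CFBP1 (Solyc10g086720.2), a chloroplast fructose-bisphosphatase, rose from 1.06 ± 0.938 to 12.7 ± 2.42 CPM (3.59 ± 0.821, adjusted p = 0.00800, 4.57 without control replicate 2). Of 26 chlorophyll synthesis genes 10 rose and 1 fell (13 and 1, median 1.02, camera adjusted p = 0.000315), the one that fell being HEMA1 (-3.79 ± 0.260, adjusted p = 2.79e-05). Ribosomal proteins of the plastid and mitochondrial type had 16 up and none down of 66 (15 and 0, median 0.48, camera adjusted p = 0.000146), including rps21 (Solyc03g110930.3, 3.07 ± 0.414, adjusted p = 0.000490). Chaperonins had 5 up and 1 down of 27 (5 and 1, median 0.32, camera adjusted p = 0.0138, 0.114 without control replicate 3, range 0.000348 to 0.114). With an estimated correlation the adjusted p of the photosystem, Calvin cycle, chlorophyll synthesis, ribosomal and chaperonin lists was 0.772 as well. The GO term chloroplast organization had 55 of 137 genes up and 1 down (camera adjusted p = 7.39e-08, 0.882 with an estimated correlation).

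Auxin genes had 50 up and 11 down of 136 (59 and 11 adjusted over the list alone, median 0.72, camera adjusted p = 0.000146, 0.772 with an estimated correlation), with GH3.6 higher by a ratio of 391 (108 to 3236, 2 counts at 0 h). The fitted log2 fold change of GH3.6 went from 8.39 to 11.17 without control replicate 2. Cytosolic ribosomal proteins had 28 up and 8 down of 235 (18 and 5, median 0.15, camera adjusted p = 0.00640, 0.832 with an estimated correlation), a call lost without control replicate 3 (0.475) and without replicate 2 of 96 h (0.0639) in a range of 1.31e-08 to 0.475. The abundant RPL3 (Solyc01g104590.3) was at 558 ± 58.0 CPM against 505 ± 123. Splicing factors had 21 up and 7 down of 78 (24 and 7, median 0.22, camera adjusted p = 0.00640, 0.772 with an estimated correlation, 0.0955 without control replicate 2, range 0.00274 to 0.0955), with SF1 (Solyc05g051990.3) at 37.0 ± 4.46 CPM against 17.1 ± 0.418 (1.11 ± 0.137, adjusted p = 0.000309). The ethylene response factor ERF4 (Solyc12g038450.1) went from 0 counts to 27.3, 10.6 and 9.37 CPM in the 3 libraries, at least 292-fold higher over the group. The fitted log2 fold change of ERF4 went from 11.27 to 10.61 without replicate 1 of 96 h.

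Of the 58 WRKY factors 35 fell and 1 rose at 96 h (38 and 1 adjusted over the list alone, median -1.43, camera adjusted p = 2.37e-11, 0.180 with an estimated correlation). Plant-pathogen interaction had 78 of 161 genes down and 6 up (camera adjusted p = 8.49e-09, 0.923 with an estimated correlation) and response to chitin 66 of 96 down and 6 up (9.42e-14, 0.646 with an estimated correlation). Phenylpropanoid and flavonoid genes had 39 down and 10 up of 99 (42 and 12, median -0.44, camera adjusted p = 0.00640, 0.772 with an estimated correlation). PAL5 (Solyc09g007900.4), the entry enzyme of the pathway, fell from 817 ± 221 CPM by 2.14 ± 0.468 (SE) on the log2 scale (adjusted p = 0.00640). The abscisic acid and dehydration list had 44 down and 10 up of 134 (45 and 10, median -0.18, camera adjusted p = 0.00807, 0.772 with an estimated correlation, 0.0639 without replicate 2 of 96 h, range 0.00271 to 0.0639). The ethylene list had 44 down and 18 up of 140 (45 and 22, 0.108, passing without control replicate 1 (0.0393), replicate 2 of 24 h (0.0432), replicate 3 of 24 h (0.0398), replicate 1 of 48 h (0.0461), replicate 3 of 48 h (0.0488) or replicate 3 of 96 h (0.0353), range 0.0353 to 0.174). The jasmonate and wound list had 18 down and 5 up of 74 (18 and 5, median -0.22, 0.0734, with 0.0213 without control replicate 1 and 0.0147 without replicate 2 of 96 h, range 0.0147 to 0.137). TIFY5A was lower by a ratio of 922 (165 to 36450, 1 count at 96 h) and ERF109 (Solyc01g108240.3) by 1943 (348 to 76790, 1 count). The fitted log2 fold change of TIFY5A went from -9.44 to -11.35 without replicate 1 of 96 h, which held its count, and to -8.82 without control replicate 3. That of ERF109 went from -10.51 to -12.45 without replicate 3 of 96 h, which held its count. Pathogenesis-related proteins had 11 up and 14 down of 92 (camera adjusted p = 0.735).

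Glutathione S-transferases had 16 down and 3 up of 54 (16 and 3 adjusted over the list alone, median -0.81, camera adjusted p = 0.00640, 0.772 with an estimated correlation, 0.0639 without replicate 2 of 96 h, range 0.00170 to 0.0639), and GSTF11 fell from 82.9 ± 27.9 to 1.63 ± 1.06 CPM (log2 fold change -5.66, -6.34 without replicate 1 of 96 h). Proteasome subunits had 15 down of 53 (14 adjusted over the list alone, median -0.38, camera adjusted p = 0.000202), with PA200 (Solyc07g066030.4) at -0.88 ± 0.203 (adjusted p = 0.00806). Chlorophyll breakdown, senescence and autophagy genes had 15 down and 2 up of 54 (15 and 2, median -0.45, camera adjusted p = 0.00285), and the senescence protease SAG12 (Solyc02g077040.4) fell from 652 ± 161 to 122 ± 40.4 CPM (-2.41 ± 0.348, adjusted p = 0.000714). Folding genes of the endoplasmic reticulum had 7 down and 1 up of 27 (7 and 1, median -0.32, camera adjusted p = 0.0138, 0.0621 without replicate 3 of 96 h, range 0.00399 to 0.0621). With an estimated correlation the adjusted p of the proteasome, breakdown and folding lists was 0.772 too.

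No heat shock protein list passed as higher by camera at 96 h. Of 26 small ones 1 rose and 4 fell (1 and 4 adjusted over the list alone), the median being 0.45 and the mean 0.07 while the camera test pointed down (adjusted p = 0.996). HSP18.5-C fell to 176 ± 46.1 CPM (-1.59 ± 0.262, adjusted p = 0.00143). The HSP70 list had 5 down (5, median -0.50, camera adjusted p = 0.108), the HSP90 and HSP100 list 1 down (0.693), the DnaJ and BAG list 15 up and 16 down (0.693) and the heat shock factor list 2 up and 6 down (0.202). HSF24 (Solyc02g090820.3) fell from 133 ± 31.1 to 19.0 ± 5.75 CPM (-2.81 ± 0.270, adjusted p = 8.75e-05). The scavenging list had 9 up and 5 down of 41 (0.620), with the minor catalase Solyc01g100630.3 at 2.77 ± 0.364 (3.36 without control replicate 3). Cell wall genes had 18 up and 20 down of 125, with a median of 0.16 and a test that pointed down (0.917), and starch and sucrose genes 6 up and 14 down of 57 (0.0711).

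No list of markers passed by camera at 96 h. Of 10 fruit ripening genes 1 rose and 2 fell (camera adjusted p = 0.693), of 182 epidermis, cuticle and trichome genes 28 rose and 21 fell (0.693), of 29 flower and pollen genes 4 rose and 1 fell (0.605), and of the 10 genes of the organelle genome and ribosomal RNA list 3 rose (0.238). By their descriptions 2 of these encode ATP synthase subunit beta and 8 are nuclear intron maturases and proteins of ribosomal RNA processing, so the list does not measure organelle or ribosomal RNA. The 50 xylem and phloem genes had 5 up and 7 down (0.131, and lower with 0.00706 without replicate 2 of 96 h, range 0.00706 to 0.378). No marker list passed by camera at 24 h or 48 h, where the lowest adjusted p-values were 0.303 and 0.221. ACO1 (Solyc07g049530.3), a ripening marker that also makes ethylene in leaves, fell from 702 ± 272 to 49.4 ± 53.8 CPM (log2 fold change -3.83, -5.25 without replicate 1 of 96 h). The edgeR count of 6794 calls ran from 4767 to 7115 over the omitted libraries. The share of higher calls was 46.9%, and 61.7% under upper quartile scaling with a median of all genes of 0.19 in place of 0.03.

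**Figure D3:**
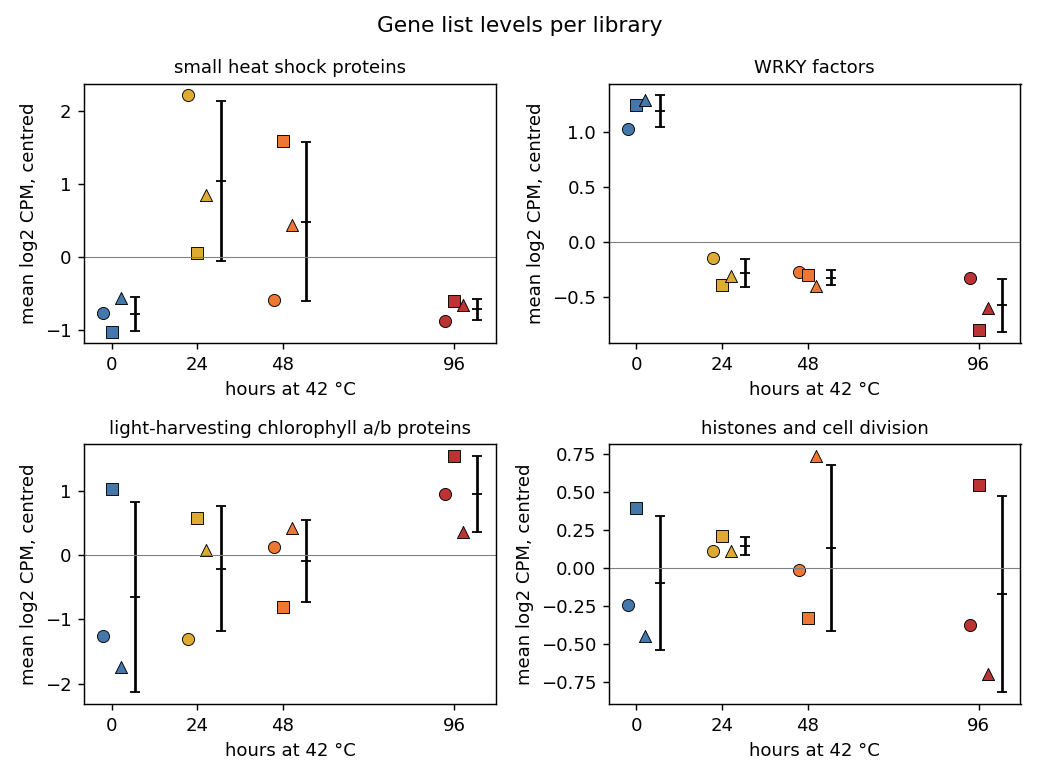
The panels plot the mean log2 CPM of a list's members, centred over the 12 libraries, against hours at 42 °C. Coloured points are single libraries, moved sideways by replicate, and black marks are means ± SD of 3, so that WRKY factors go from 1.19 ± 0.143 at 0 h to -0.58 ± 0.241 at 96 h while small heat shock proteins spread by 1.09 (SD) at 24 h.

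The 3 comparisons with 0 h overlapped. At one heat time or more 3535 genes were called higher and 3920 lower. At all 3 times 652 were higher and 1183 lower, 1723 were higher and 1591 lower at 96 h alone by this threshold, which does not test a difference between times, and 3 were called in opposite directions. The counts at all 3 times fell to 297 and 713 without replicate 2 of 24 h, 308 and 761 without replicate 3 of 24 h and 322 and 775 without control replicate 3, and without control replicate 1 the first fell to 338. The 24 h and 48 h comparisons shared 736 genes higher and 1241 lower, where independent lists would share 72.5 and 148. Sets simulated without any change, with controls drawn anew, shared at most 1 and 0. Genes without a change are rarely called at this threshold, so these counts are no baseline for the overlap of real calls. For 24 h and 96 h the shared counts were 736 and 1278 (143 and 253 if independent), and for 48 h and 96 h 1380 and 1921 (247 and 366 if independent). Correlations of fold changes across genes were 0.848, 0.768 and 0.880 against 0.505, 0.504 and 0.507 in the simulation, with covariances of 0.985, 1.05 and 1.32 against 0.113, 0.114 and 0.114. The simulated correlations and covariances show what shared controls give when genes vary independently, which genes of these 3 control libraries need not do. The 3 control libraries are too few to give each comparison 2 controls of its own. Part of the overlap may therefore come from the shared controls, and how much was not measured.

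Between neighbouring heat times almost no single gene was called. From 24 h to 48 h 1 gene fell, WRKY3 (Solyc02g088340.4), from 20.3 ± 2.62 to 7.37 ± 0.110 CPM (log2 fold change -1.46 ± 0.159 SE, n = 3 per group, edgeR adjusted p = 0.0450). The number of called genes was 0 without control replicate 1, 2 or 3, without replicate 1 or 2 of 24 h, without any single 48 h library and without replicate 2 of 96 h, and 3 without replicate 3 of 24 h. At an unadjusted p under 0.05 there were 1905 genes, and DESeq2 called 248. From 48 h to 96 h edgeR called 0 genes, with 2497 at an unadjusted p under 0.05 and 810 calls by DESeq2. It called 33 genes without replicate 1 of 48 h, 8 without replicate 1 of 96 h and 4 without control replicate 1.

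By camera at the preset correlation 5 lists passed from 24 h to 48 h and 17 from 48 h to 96 h. None held with an estimated correlation (adjusted p = 0.910 and 0.758 for those named), and the test fry passed 0 lists in both comparisons. From 48 h to 96 h the light-harvesting list was higher by a median of 0.81 (camera adjusted p = 7.48e-07) and the list of plastid and mitochondrial type ribosomal proteins by 0.53 (8.28e-10), and small heat shock proteins were lower by a median of -1.54 (4.25e-05). From 24 h to 48 h cytosolic ribosomal proteins were higher by 0.22 (2.66e-11) and proteasome subunits lower by a median of -0.19 (0.000547). The proteasome call was lost without replicate 1 of 48 h (0.0718) and without replicate 1 of 24 h (0.839), where the direction also turned, in a range of 4.38e-09 to 0.839. No marker list passed in these comparisons with all libraries. From 48 h to 96 h the xylem and phloem markers passed as lower without replicate 2 of 96 h (0.00136, range 0.00136 to 0.953). The epidermis, cuticle and trichome markers passed as lower without replicate 2 of 96 h (0.00328) or replicate 2 of 48 h (0.00782, range 0.00328 to 0.917), and from 24 h to 48 h as higher without replicate 2 of 48 h (0.0270, range 0.0270 to 0.993).

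Compared over the longer span from 24 h to 96 h, a comparison added after the data were seen, 495 genes rose and 634 fell (221 and 406 at least 2-fold, DESeq2 3285 in all). The share of higher calls was 43.8%. It was 53.5% with upper quartile scaling (643 higher and 559 lower), so that the balance turned. It was 32.7% on log2(FPKM + 1) and 29.0% on log2(FPKM + 0.1). The median of all genes was 0.05, -0.10 and -0.13 in these settings in place of 0.01. CBSCBSPB4 rose from 0.136 ± 0.108 to 23.6 ± 5.59 CPM (log2 fold change 7.39 ± 0.663 SE, n = 3 per group, edgeR adjusted p = 0.00987, 8.19 without replicate 2 of 24 h), and UGT75C1 (Solyc12g098590.3), a sugar transferase, fell from 10.7 ± 2.95 to 0.242 ± 0.175 CPM (-5.39 ± 0.527, adjusted p = 0.00515). These 2 were called whichever single library was left out, and the other 36 of the 38 called genes among the 73 that the rule names in this comparison were not. Many of these losses came without a control or 48 h library, which is outside this comparison. Such losses reflect the shared estimate of spread and the adjustment, not a change in the compared groups. Cytosolic ribosomal proteins had 20 up and none down of 235 (46 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 3.96e-19). Small heat shock proteins had 4 down of 26 (17 adjusted over the list alone, median -2.07, camera adjusted p = 1.01e-05). The organelle genome and ribosomal RNA list, the one marker list that passed with all libraries, had 1 up of 10 (median 0.22, 0.0460). It was lost without control replicate 2 (0.0527), replicate 1 of 24 h (0.177), replicate 1 (0.0511) or 2 (0.0553) of 48 h and replicate 1 (0.0764) or 2 (0.0511) of 96 h, in a range of 0.0241 to 0.177. The xylem and phloem markers passed as lower without replicate 2 of 96 h (0.0160, range 0.0160 to 0.936). None of the 20 list calls held with an estimated correlation, the adjusted p being 0.671 for these 3 lists, and fry passed 2 lists. The count of 1129 was 5 without replicate 3 of 96 h, 180, 195 and 253 without replicates 2, 1 and 3 of 24 h, 402 without replicate 1 of 96 h, 571 and 658 without control replicates 1 and 3, and 1958 without control replicate 2.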

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

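The tests of a single 0 h library, the hour of day, a single 24 h library and paralogs were chosen after the results were seen. So were those of dividing tissue and the relations of all lists, and the comparison of 96 h with 24 h. The other splits were chosen before. The predictions for depth and multiply mapped reads were written before their outcome was known. They concern a pattern already seen in these data, the shared deviations of libraries of different heat times.

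Levels differed between heat times, by a direct test of the difference with camera at the preset correlation, in these results. With an estimated correlation 0 lists passed in these comparisons, and with fry 0 from 24 h to 48 h, 0 from 48 h to 96 h and 2 from 24 h to 96 h. For small heat shock proteins the camera adjusted p was 0.0470 from 24 h to 48 h, 4.25e-05 from 48 h to 96 h and 1.01e-05 from 24 h to 96 h. The first was lost without control replicate 2 (0.0557) or 3 (0.0507), replicate 1 (0.915) or 3 (0.0626) of 24 h, replicate 1 (0.825) or 3 (0.0980) of 48 h and replicate 2 (0.0517) or 3 (0.0526) of 96 h. For light-harvesting proteins it was 7.48e-07 from 48 h and 0.000259 from 24 h to 96 h (0.0803 without replicate 1 of 24 h), for photosystem subunits 6.77e-05 and 0.00115 (0.150 without replicate 1 of 24 h) and for Calvin cycle enzymes 9.24e-05 and 0.000560. For the jasmonate and wound list it was 0.000302 and 0.0456, the latter lost without control replicate 2 (0.0527), replicate 2 (0.222) or 3 (0.234) of 24 h, replicate 2 of 48 h (0.0610) and replicate 1 (0.147) or 3 (0.187) of 96 h. For HSP90 and HSP100 proteins it was 0.0209 from 24 h to 96 h (0.185 without replicate 1 of 24 h).

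Named genes that differed between 24 h and 96 h by edgeR were a 17.3 kDa class II heat shock protein (Solyc08g062340.3, log2 fold change -6.46), ClpB1 (Solyc03g115230.3, -2.28), HSFA2b (Solyc09g065660.4, -3.27), ribose-5-phosphate isomerase RPI4 (Solyc02g069620.4, 1.64), ascorbate peroxidase APX1 (Solyc06g005160.4, -1.34), a wound-induced proteinase inhibitor (Solyc09g089540.4, -8.41) and a glucan endo-1,3-beta-glucosidase (Solyc01g101120.4, 1.90). Of the 12 fits that each left out a library, the calls were lost in 8, 8, 5, 9, 1, 9 and 4, in that order. Losses without a control or 48 h library leave both compared groups whole and the fold changes nearly the same. They reflect the shared estimate of spread and the adjustment over genes. Without replicate 1 of 24 h the fold changes of the first 4 were -3.66, -1.40, -2.86 and 1.51, and none of these calls held. That of the 17.3 kDa protein was also lost without control replicate 1 (-6.46) or 3 (-6.46), replicate 3 of 24 h (-6.93), replicate 3 of 48 h (-6.46) and replicate 1 (-6.40), 2 (-6.84) or 3 (-6.21) of 96 h. That of ClpB1 was lost without the same libraries, at -2.47 to -2.20. HSFA2b was lost without replicate 2 (-3.35) or 3 (-3.53) of 24 h and replicate 1 (-2.95) or 3 (-2.85) of 96 h, and was at -4.55 without replicate 2 of 96 h. RPI4 was lost without control replicate 1 (1.63) or 3 (1.63), replicate 2 (1.58) or 3 (1.82) of 24 h, replicate 1 (1.64) or 3 (1.64) of 48 h and replicate 1 (1.57) or 3 (1.47) of 96 h. The proteinase inhibitor moved most without replicate 3 of 24 h (-6.27) and replicate 2 of 96 h (-9.62). Its call was lost there and without control replicate 1 (-8.42) or 3 (-8.42), replicate 2 of 24 h (-8.76), replicate 2 (-8.41) or 3 (-8.40) of 48 h and replicate 1 (-7.84) or 3 (-8.30) of 96 h, and without replicate 1 of 24 h the fold change was -8.997. That of APX1 was lost without replicate 3 of 96 h (-1.19), and that of the glucosidase without replicate 1 (1.81), 2 (1.99) or 3 (1.87) of 24 h or replicate 3 of 96 h (1.96).

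The WRKY list passed as lower than at 0 h at all 3 heat times by camera at the preset correlation, and at none with an estimated one (adjusted p = 0.0873, 0.123 and 0.180). A single 0 h library as the source is argued against, because the median of the list was -0.986 or lower without each control. Another hour of day at 0 h stays open. The heat times are whole days after 0 h, which puts all groups at the same hour if these times were kept exactly. Clock genes were called at 24 h in 16.7% of cases against 11.5% of other genes (one-sided Fisher exact p = 0.343, the lowest of 3), too few members to exclude a shift, and the labels give no hour. The centred mean log2 CPM of the clock list was 0.233 or higher in the controls and 0.0521 or lower in every heated library. Its median log2 fold changes at 24, 48 and 96 h were -0.220, 0.048 and -0.0605. Heat itself is the biological explanation that the design names. It could not be separated from plant age, or from any difference in the hour, as no unheated leaves were taken after 0 h.

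The list of small heat shock proteins passed as higher at 24 h than at 0 h by camera at the preset correlation, and not with an estimated one (adjusted p = 0.980). A single 24 h library is argued against, because the median was 1.99 or higher without each. Reads shared between paralogs cannot be told apart from a rise of single members. The summed CPM of the list at 24 h was 1.79 times that at 0 h, but in replicate 2 of 24 h it was 591, below each of the 3 controls. The most abundant member, HSP18.5-C, made up most of this sum at 0 h, and its mean was lower at 24 h without passing. A sum carried by a single member cannot decide on reads shared among the members that rose.

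Libraries of different heat times deviated from their group means together, without a clear pairing by replicate number. Thinning could not decide on depth, because totals ran only from 18370928 to 20808466 counts and little was removed. Replicate 3 of 48 h (19592206 counts) and replicate 2 of 96 h (19538030) correlated across genes at 0.718 before thinning. After all libraries were thinned to 18370928 counts the correlation was 0.717. The share of dividing young leaf tissue stays open, although over 12 libraries the deviation followed the histone and cell division list (Pearson r = 0.935, exact within-group permutation p = 0.00540, adjusted over 39 relations 0.0211, Spearman rho = 0.867, permutation p = 0.00231, r = 0.838 without the 2 farthest libraries). In all 13 of 38 lists passed in this way, among them epidermis, cuticle and trichomes (r = 0.970, rho = 0.979, r = 0.918 without the 2 farthest) and xylem and phloem (r = 0.945, rho = 0.965, r = 0.853 without the 2 farthest, for both lists permutation p = 0.000772, the smallest these orders can give, for r and rho, adjusted 0.01003 for r), so the relation does not single out dividing tissue. Multiply mapped reads stay open (r = 0.332, permutation p = 0.230, adjusted 0.359, rho = 0.357, permutation p = 0.230, r = 0.213 without the 2 farthest).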

How the results depend on the processing

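The comparison of 96 h with 24 h, the omission of library pairs, log2(FPKM + 0.1) for lists and the omissions for sample structure and overlaps were chosen after the results were seen. The total of calls against 0 h kept within 1.5 times its number under DESeq2 size factors, upper quartile scaling, both filters, the omission of the 50 most abundant genes and both FPKM settings. Higher calls alone moved further. With upper quartile scaling they went from 935 to 1509 at 24 h and from 1613 to 2750 at 48 h. At 48 h they were 2501 on log2(FPKM + 1) and 2636 on log2(FPKM + 0.1), where lower calls went from 2113 to 1437 and 1397. Where a cause is not named below, the cause was not tested.

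With an estimated correlation 0 lists passed in each of the 6 comparisons, and with fry 0 passed from 24 h to 48 h, 0 from 48 h to 96 h and 2 from 24 h to 96 h. Of the 6, 6 and 16 list calls at 24, 48 and 96 h, fry did not pass 3, 2 and 8, and it passed 3, 5 and 7 others. From 24 h to 48 h the count of 1 gene became 0 with DESeq2 size factors, upper quartile scaling, the 2 groups alone, the replicate block, the 50 most abundant genes left out, an adjusted p under 0.01, log2(FPKM + 1) and either pair of libraries left out. From 48 h to 96 h the count of 0 became 15 without a filter, 17 at 10 CPM, 68 on log2(FPKM + 1) and 89 on log2(FPKM + 0.1). The share of the first component, 41.2%, became 37.7% without a filter and 50.2% at 10 CPM. Lists called at 48 h went from 6 to 10 at 10 CPM and to 10 on log2(FPKM + 1). DESeq2 called 3931 genes at 24 h, 248 from 24 h to 48 h, 810 from 48 h to 96 h, 3285 from 24 h to 96 h and 7998 in its joint test. The 2 groups alone gave 2370 at 48 h and 348 from 24 h to 96 h, with fewer libraries to estimate the spread, and the joint test was not run there.

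The replicate block gave 236 from 24 h to 96 h. The replicate numbers gave no clear pairing of the libraries. Of 18 pairs of one number 8 correlated above 0.1, in a range of -0.624 to 0.325, and 2 libraries were closest to their own number. No reference without pairing was computed for these values, so they do not exclude a partial pairing. At an adjusted p under 0.01, a stricter threshold by construction, the counts were 930, 1461 and 3457 against 0 h, 4 from 24 h to 96 h, 2088 in the joint test and 165 higher and 583 lower at all 3 times. At a 2-fold minimum 333 were higher at all 3. Without replicate 3 of 48 h and replicate 2 of 96 h, 8 lists passed from 24 h to 48 h. Without replicate 1 of 24 h and replicate 2 of 48 h, 206 genes were called from 24 h to 96 h, and 15, 13 and 9 lists at 24 h, at 48 h and from 24 h to 48 h.

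Over the 12 omissions of a library the joint test called 3034 to 5302 genes. The counts ran from 1191 to 2786 at 24 h, 2132 to 4181 at 48 h, 4767 to 7115 at 96 h, 0 to 3 from 24 h to 48 h, 0 to 33 from 48 h to 96 h and 5 to 1958 from 24 h to 96 h. At all 3 times 297 to 649 were higher and 713 to 1255 lower. Lists called ran from 6 to 14, 6 to 16 and 13 to 17 against 0 h, 3 to 11 from 24 h to 48 h, 12 to 18 from 48 h to 96 h and 16 to 21 from 24 h to 96 h. The share of the first component ran from 35.2% to 43.9%. A list turned direction in 4 cases, cytosolic ribosomal proteins at 48 h without control replicate 2 (adjusted p = 0.00610, range 0.00610 to 0.714 over the omissions), photosystem (0.0294, range 0.0294 to 0.964) and proteasome subunits (0.839, range 4.38e-09 to 0.839) from 24 h to 48 h without replicate 1 of 24 h, and histones from 48 h to 96 h without replicate 3 of 48 h (0.684, range 1.83e-07 to 0.962).

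The share of higher calls at 24, 48 and 96 h was 39.1%, 43.3% and 46.9%, and 54.9%, 62.6% and 61.7% with upper quartile scaling. With log2(FPKM + 1) it was 53.8%, 63.5% and 50.9%, and with log2(FPKM + 0.1) 56.8%, 65.4% and 51.6%. Of results for a named gene in a comparison, upper quartile scaling left 311 on the same side of the threshold, 4 passed newly and 3 were lost. In the simulation of 24 h against 0 h edgeR called 25% of 2-fold changes and DESeq2 46%. Far fewer genes were changed there than were called in the real comparison, so these shares need not hold for it. What depth alone limits was not separated from the spread between libraries and the tool.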

Other observations

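The term tests were planned, as were the other splits of the samples. Genes annotated with the regulation of salicylic acid synthesis were lower at 24, 48 and 96 h, with 9, 11 and 11 of 16 down and none up (camera adjusted p = 1.90e-05, 2.90e-07 and 1.77e-06). Regulation of jasmonic acid signalling had 12, 12 and 14 of 30 down (2.38e-07, 9.55e-05 and 0.000103). Auxin polar transport had 6 of 41 up and 1 down at 24 h (0.0106) and 8 up and 2 down at 48 h (0.00405). Meiotic recombination genes had 6 and 8 of 45 up at 24 h and 48 h (0.0193 and 0.00355). Termination of DNA-templated transcription had 8 of 21 up at 48 h (0.00405) and 11 up and 1 down at 96 h (0.00278). Oxidative phosphorylation had 13 of 106 down and 2 up at 48 h (0.00420), and endocytosis 54 of 166 down and 10 up at 96 h (0.00174). None of these passed with an estimated correlation, where the lowest adjusted p was 0.560.

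The 10 splits of the 6 libraries of a comparison are too few for a share under 0.05. The real split called 2392 genes at 24 h, 3726 at 48 h and 6794 at 96 h, and in each comparison it was the 1 split of 10 to call as many, the highest other being 53, 6 and 1. From 24 h to 48 h the real split called 1 gene, with 1 split of 10 calling as many and 0 as the highest other. From 24 h to 96 h the real split called 1129 and the highest other 0. From 48 h to 96 h it called 0, which all 10 splits reached, the highest other calling 2. For the joint test 1 of 100 splits, the real one, called as many as 5099 genes, a share under 0.05. This argues against chance for the 4 groups as a whole, and does not show which groups carry the difference. The highest others called 4916, 3148 and 2870, and which libraries such splits kept together was not examined.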
